A study of Mus musculus with 5 samples.

How the data were processed

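The series measured DNA methylation in primary CD8+ T cells, the cytotoxic lymphocytes, of C57BL/6 mice. Per the labels, naive T cells from spleen were cultured, sorted as individual CD8+ cells, and each founder cell was expanded into a clone. The 5 samples fall into 3 groups: 1 sample of the original non-clonal population, 2 replicates of clone 1 and 2 replicates of clone 2. The labels give 15 cell divisions for the clones. Genomic DNA was cut with MspI, an enzyme that cuts at CCGG whether or not its inner CpG is methylated, ligated into a plasmid library of molecular tags, converted with bisulfite and amplified, per the labels' protocols. Bisulfite turns unmethylated cytosines into uracils and leaves methylated ones, so each sequenced molecule carries a methylated or unmethylated call at each CpG.

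The 3 deposited files have no header. The files themselves show 1 line per restriction fragment number, strand and tag of 6 bases, with a string that holds 1 character per CpG of the fragment (0, 1 or not observed). The authors' values next to it are a count of reads behind that tag, read here as the reads of 1 molecule, and a whole number of unstated meaning that never exceeds that count. The deposited counts are not normalized. The submitters' processing notes name Bismark and the mouse build mm9. The Bismark version, the filters and the way replicates were combined are not given in the sources used here. Each clone's 2 replicates share 1 deposited file and cannot be told apart in it, so each clone entered as 1 pooled library. Tests on molecules therefore compare these 3 libraries, not conditions, and no spread between replicates could be had.

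The files give no coordinates, and the reference held here, a gene name table of another build, has no column that matches fragment numbers. Fragments are therefore named by number, with no chromosome, gene or other annotation, and no gene list was tested (15 lists had been fixed beforehand). Promoters were replaced by the fallback fixed with them, regions of at least 4 CpGs, taken here as single fragments with at least 4 CpGs. Bootstrap intervals resampled blocks of 1000 consecutive fragment numbers in place of chromosomes, with 1000 draws and 95% confidence. Exceptions were the correlations between fragments, which resampled single pairs with fewer draws, and the coverage of fragments in runs, which resampled single fragments. Neither kept neighbours together, so those intervals may be too narrow.

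Each tag on a strand of a fragment counted as 1 molecule. Molecules on opposite strands with the same tag were kept apart: calls of same-tag pairs and of other tags matched about equally often, with differences of 0.0301 percentage points in the population, -0.101 in clone 1 and -0.0285 in clone 2. The files use 77 tags, unevenly, equal to 45.6, 46.2 and 45.4 even ones in the population, clone 1 and clone 2. Separate molecules can therefore share a tag on deep fragments and be merged. Strands with over 25 molecules held 2.52%, 8.88% and 6.46% of molecules in the same order. Calls at fragment ends rebuilt by the fill-in reaction made up 0.292%, 0.475% and 0.730% of calls and were kept.

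CpGs were compared by a two-sided Fisher's exact test on methylated and unmethylated molecules, with at least 10 molecules in both libraries and Benjamini-Hochberg adjustment over all CpGs tested. A call needed an adjusted p under 0.05 and a difference of at least 20 percentage points. Fragments with at least 4 CpGs were compared in the same way on molecules with more than 50% of their observed CpGs methylated. The named fragments are the 5 called ones per direction and comparison with the widest difference. The first 2 per direction are drawn in a figure, and some of the 5 are given in the text. CpGs at 20 to 80% in the population are called intermediate. To avoid regression to the mean, the population's molecules were divided at random into 2 parts, each with at least 5 molecules at the CpG. One part chose the intermediate CpGs and the other gave the level p that the clones were compared with. The variance ratio is the sum of squared clone deviations from p, less the counting variance of both libraries, over the sum of p(1-p). It is 0 for a clone that matches the population. The residual ratio is the sum of p(1-p) within the clone over that of the population. The covariance ratio replaces the square with the product of both clones' deviations, less the counting variance of the population library they share. CpGs called against 1 part of the population were set beside all tested CpGs in the same 20 classes of population level and 3 classes of CpGs per fragment, with levels from at least 3 molecules that entered neither the call nor the match. Epipolymorphism, the chance that 2 molecules of a library carry different patterns over 4 consecutive CpGs, was averaged over windows with at least 10 molecules in every library.

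The call test, the ratios and epipolymorphism were tested on simulated data before use. With 200 CpGs changed per comparison, changes of 80 percentage points were called at 56.1% (clone 1 against the population, 801448 CpGs), 65.2% (clone 2, 681261) and 65.2% (clone 1 against clone 2, 779287). Changes of 50 points were called at 5.97%, 7.46% and 17.9%, changes of 30 points at 0%, 0% and 4.48%, and no unchanged CpG was called. The simulation drew counting error alone and changed few CpGs, which makes the adjusted threshold stricter than in the data. These rates therefore do not give the share of changes found, or of false calls, in the data. Simulated clones that kept 2 independent founder alleles gave variance ratios of 0.503 and 0.504. Simulated unchanged clones gave -0.000209 and 0.00101.

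Alternatives changed the coverage minimum, the minimum difference, the depth, the strand, the CpGs and molecules admitted, the range taken as intermediate and the window rules. Numba 0.67.0, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used under Python 3.11.15, with random seed 20140. Intervals cover counting error or the spread over fragments, not culture, animal or library preparation.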

Results

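DNA methylation of mouse CD8+ T cells was measured in a non-clonal population and in 2 clones, each grown from 1 founder cell over 15 cell divisions. The design asks how methylation varied in a clone relative to the population it came from. The population library listed 8463942 molecules from 17003711 reads, clone 1 listed 11969176 from 16036644, and clone 2 listed 8977287 from 15027960. A CpG call was present on 5588357, 7013054 and 5567534 molecules respectively. The median CpG was covered by 7 molecules in the population, 7 in clone 1 and 5 in clone 2. At least 10 molecules covered 960838, 1017469 and 856516 CpGs. Each clone's 2 replicates entered as 1 pooled library and the population had 1 replicate, so no value has a spread between replicates.

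In all 3 libraries, fragments with more CpGs had lower methylation. At 654632 CpGs covered in all of them, fragments with 2 to 4 CpGs were 83.6% methylated in the population, 84.2% in clone 1 and 85.3% in clone 2. Fragments with 5 to 9 CpGs stood at 67.8%, 69.0% and 69.8%, and fragments with 10 or more CpGs, called dense here without regard to their length, at 16.1%, 17.1% and 17.1%. The mean over all these CpGs was 49.5% (95% interval 48.8 to 50.1) in the population. It was higher by 1.04 percentage points in clone 1 (0.964 to 1.11) and by 1.56 in clone 2 (1.499 to 1.63). Clone 1 lay 0.690 points above the population on fragments with 2 to 4 CpGs and 0.986 above it on the dense ones, against 1.76 and 1.08 for clone 2.

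Single CpGs of clone 1 departed from the population in both directions. Of 801448 CpGs tested, 14992 passed, 8486 with a higher level in clone 1 and 6506 with a lower one. The median difference among them was 55.1 percentage points. On dense fragments 2919 called CpGs were higher and 650 lower, and on fragments with 2 to 4 CpGs 1531 were higher and 2497 lower. Direction followed the starting level, since called CpGs under 20% in the population could only be higher (3742) and those over 80% only lower (3699). Among CpGs intermediate in the population, dense fragments had 1060 higher and 385 lower from a mean of 44.8%, and fragments with 2 to 4 CpGs 1163 and 1052 from a mean of 61.3%. CpGs intermediate in the population were called at 7.40%, against 1.16% of those under 20% and 0.982% of those over 80%. The calls rest on Fisher's exact test with Benjamini-Hochberg adjustment, at a median of 27 clone and 21 population molecules per called CpG. Higher calls were 56.6% of the total, but 45.2% with a coverage minimum of 30 and 42.3% with 1 CpG per fragment, so the balance of direction in clone 1 depended on the CpGs counted.

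Clone 2 also departed from the population in both directions. Of 681261 CpGs tested, 11712 passed, 7523 higher and 4189 lower than the population. Called CpGs on dense fragments numbered 2487 higher and 516 lower, and those on fragments with 2 to 4 CpGs 1374 higher and 1490 lower. Intermediate CpGs were called at 6.96%, with 780 higher and 316 lower on dense fragments and 1034 higher and 643 lower on fragments with 2 to 4 CpGs. The test was the one used for clone 1, with medians of 25 and 22 molecules at called CpGs. Higher calls were 64.2% of the total and 51.4% with 1 CpG per fragment.

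At CpGs intermediate in the population, each clone moved towards the extremes. Among 25711 such CpGs compared at 10 molecules each, the share with 9 or 10 methylated molecules was 22.8% in the population (95% interval 21.9 to 23.7), 37.7% in clone 1 (36.4 to 38.8) and 40.9% in clone 2 (39.5 to 42.1). The share with 0 or 1 was 7.50%, 13.8% and 12.7%. Levels between these extremes and the middle, with 2 to 3 or 7 to 8 methylated molecules, fell from 40.1% of CpGs to 26.0% and 25.8%. The middle class with 4 to 6 fell less, from 29.6% to 22.4% and 20.5%. Middle levels across all CpGs were in contrast more frequent in the clones: 4.34% and 4.10% of the 654632 CpGs lay at 40 to 60%, against 3.15% in the population.

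**Figure D1:**
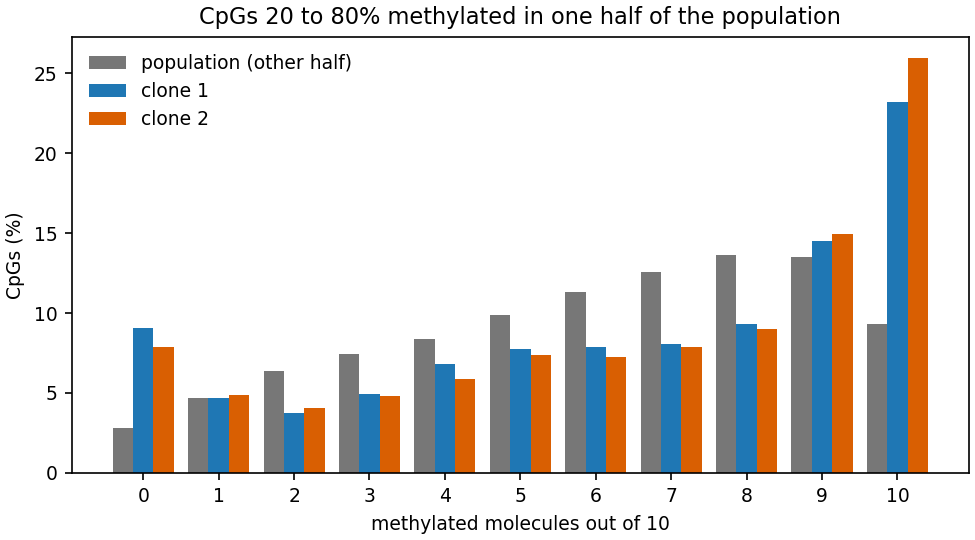
Share of CpGs (%) by number of methylated molecules out of 10, at 25711 CpGs that were 20 to 80% methylated in a separate random part of the population. Bars stand for the remaining population molecules, clone 1 and clone 2, and the clones have more CpGs at 9 or 10 methylated molecules (37.7% and 40.9%, against 22.8%).

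The variance ratio was 0.304 in clone 1 (95% interval 0.297 to 0.311, 98662 CpGs) and 0.310 in clone 2 (0.303 to 0.317, 81112 CpGs). Variation between molecules within the clones remained below that of the population, with residual ratios of 0.728 in clone 1 and 0.709 in clone 2. The ratio was highest at CpGs at 20 to 40% in the population, with 0.380 and 0.395, and lowest at 60 to 80%, with 0.256 and 0.2501. Being relative to p(1-p), it does not rank these CpGs by deviation in percentage points. Ratios on dense fragments were 0.316 and 0.313, and on fragments with 2 to 4 CpGs 0.284 and 0.291. The mean at intermediate CpGs was 3.40 points higher in clone 1 (3.12 to 3.69) and 5.12 points higher in clone 2 (4.82 to 5.39). The background, measured between 2 random parts of the population, was -0.00136 (-0.00724 to 0.00499). Plus and minus strands of 1 library differed by 0.0291 in the population, 0.0368 in clone 1 and 0.0382 in clone 2.

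**Figure D2:**
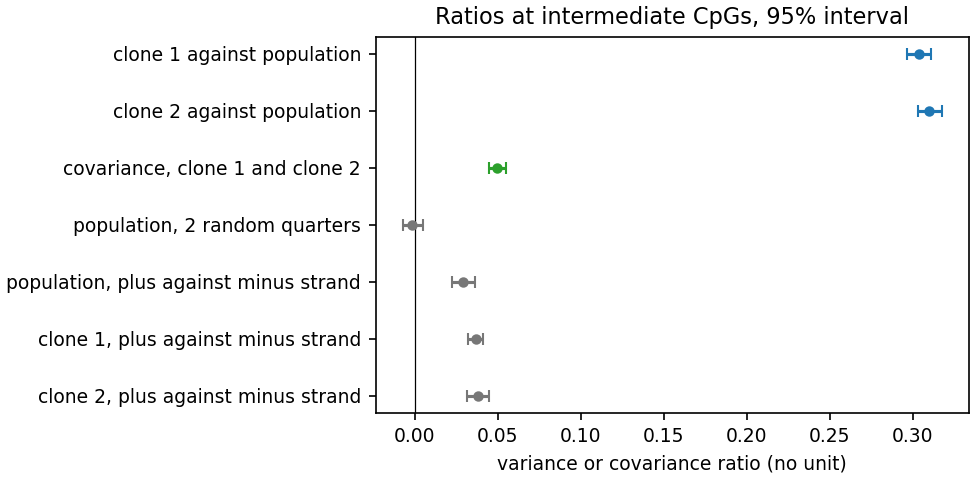
Variance ratio of each clone against the population, covariance ratio of the clones, and background ratios within libraries (no unit), at CpGs intermediate in the population. Points are estimates and bars 95% bootstrap intervals; the clones sit at 0.304 and 0.310, the covariance at 0.0495 and the strand backgrounds at 0.0291 to 0.0382.

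More CpGs were called between the clones than between either clone and the population. Clone 1 and clone 2 differed at 41997 of 779287 CpGs, 19934 higher in clone 1 and 22063 higher in clone 2. Dense fragments were even, with 5653 and 5606, and fragments with 5 to 9 CpGs had 9046 and 10372. With every library thinned to 10 molecules, 3988 CpGs separated the clones, against 217 and 180 for the clones against the population. At that depth only near-complete opposite states can pass the adjusted threshold. A CpG intermediate in the population cannot show them against it, while 2 clones can. At full depth, too, 2 clones with opposite complete states differ by more than either does from an intermediate population. Neither the thinned nor the full counts therefore rank the comparisons by how far the libraries diverged. Fisher's exact test with the same thresholds was used, at medians of 26 and 23 molecules per called CpG.

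Part of the departure from the population was common to both clones. Of 654632 CpGs tested in both, 1426 were higher in both clones and 392 lower in both, against 85.8 and 35.7 for independent lists. Simulated unchanged clones had 0 calls in either clone and so left no overlap to compare with. Independent lists within classes of population level and CpGs per fragment gave 422.2 and 99.7. In opposite directions there were 266 CpGs, against 229.1 within the same classes. To keep choice and measurement apart, CpGs were also called against 1 random part of the population, and their levels taken from a separate part. At 2033 CpGs called higher in clone 1, clone 2 was 11.99 percentage points above that part. At CpGs matched on level and CpGs per fragment clone 2 was 6.32 points above it, which left 5.68 points (95% interval 3.98 to 7.48). At 1957 called higher in clone 2, clone 1 was 11.2 points above, 6.55 beyond matched CpGs (4.89 to 8.26). At 1590 called lower in clone 1, clone 2 was 2.26 points above the population (0.624 to 3.74) and differed from matched CpGs by -1.07 points, with an interval that holds 0 (-2.67 to 0.399). At 1088 called lower in clone 2, clone 1 differed from the population by -1.19 points, with an interval that holds 0 (-3.00 to 0.672), and from matched CpGs by -2.82 points (-4.69 to -0.981). The covariance ratio was 0.0495 (95% interval 0.0450 to 0.0549), against 0.000898 for simulated unchanged clones, which carry counting error alone. The libraries held noise beyond that, with variance ratios of 0.0291 to 0.0382 between strands of 1 library. Both lists share 1 population library that could not be split into separate libraries, so part of the excess overlap may come from it.

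**Figure D3:**
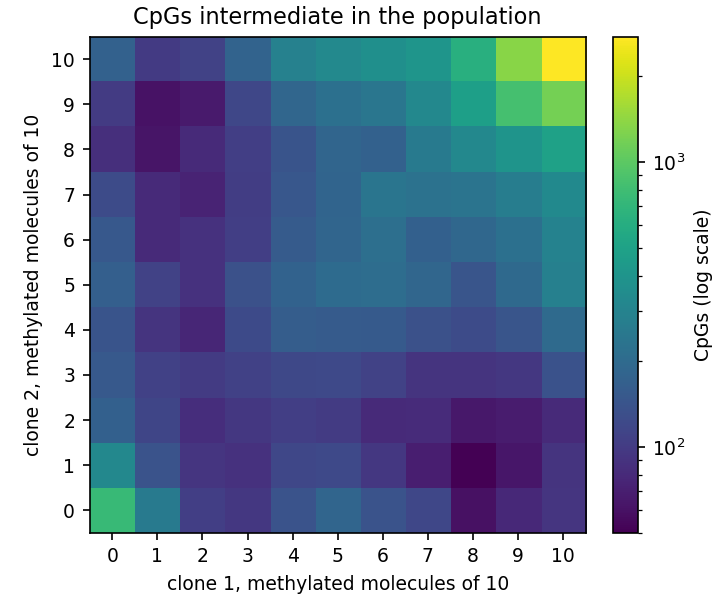
Number of intermediate CpGs (colour, log scale) by methylated molecules out of 10 in clone 1 (horizontal) and clone 2 (vertical), 25711 CpGs. Near-complete methylation in both clones (9 or 10 of 10) held 23.9% of CpGs, against 15.5% if independent. The class with 0 or 1 of 10 in both held 5.71%, against 1.76%. These expected shares were not matched on population level, so the excesses do not measure a shared departure from the population.

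Whole fragments also differed from the population. Of 139720 fragments with at least 4 CpGs, 1539 differed between clone 1 and the population, 1032 higher and 507 lower in clone 1. Of 115801, 1368 differed in clone 2, 995 higher and 373 lower. Fragments at 20 to 80% in the population made up 57.5% and 56.7% of these calls, and 17316 and 13312 of the fragments tested. They were called at 5.11% and 5.82%, against 1.10% and 1.18% of all fragments tested. In clone 1, 196 of the called fragments lay at 10% or less, 533 at 90% or more and 225 at 40 to 60%, and in clone 2 these were 141, 487 and 203. The fragments named here are those with the widest differences. Fragment 331717, with 4 CpGs, had 0 of 12 methylated molecules in the population (Wilson 95% interval 0 to 24.2%), 42 of 42 in clone 1 (91.6 to 100%) and 11 of 15 in clone 2. Fragment 998893, with 5 CpGs, fell from 31 of 32 molecules in the population to 1 of 32 in clone 1 (adjusted p 5.21e-11, Fisher's exact test), with 17 of 18 in clone 2. Fragment 689517 had 0 of 13 in the population and 13 of 13 in clone 2, with 1 of 17 in clone 1. Fragment 1440069 fell from 24 of 24 to 5 of 52 in clone 2 (adjusted p 3.65e-10, Fisher's exact test), with 43 of 46 in clone 1. Called by the deepest single CpG of each fragment, the share of higher calls was 46.4% in clone 1 and 54.4% in clone 2, against 67.1% and 72.7% by whole molecules.

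Between the clones, 3188 of 129568 fragments differed, 1466 higher in clone 1 and 1722 higher in clone 2. Fragments with opposite, complete states in the clones led this list. Fragment 1002274, with 13 CpGs, was methylated on 22 of 22 molecules in clone 1 and 0 of 27 in clone 2, and on 2 of 10 in the population. Fragment 1177979 had 18 of 18 and 0 of 19, and 7 of 13 in the population. Fragment 774496 had 0 of 27 in clone 1 and 31 of 31 in clone 2 (adjusted p 2.24e-13, Fisher's exact test), and 7 of 18 in the population. Fragment 623690, with 12 CpGs, had 0 of 25 and 22 of 22, and 19 of 31 in the population.

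**Figure D4:**
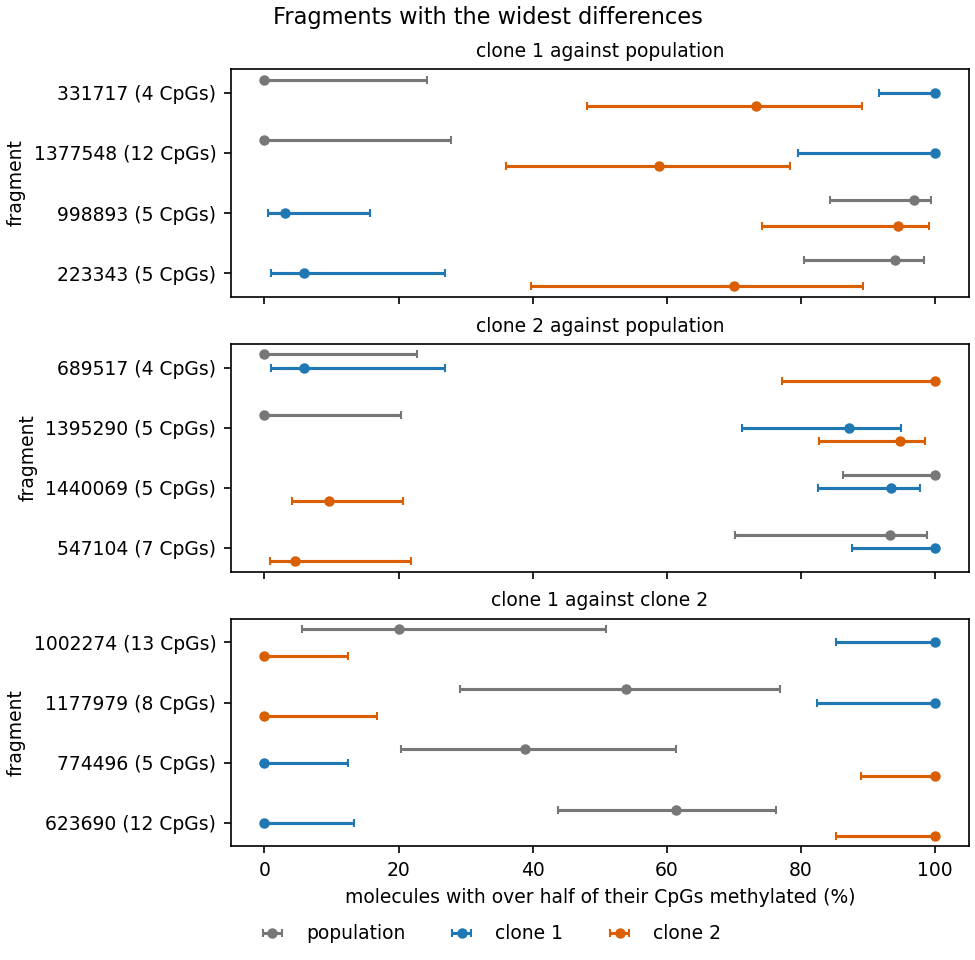
Share of molecules (%) with more than 50% of their CpGs methylated on named fragments, the first 2 higher and 2 lower per comparison. Points are the population, clone 1 and clone 2, bars are Wilson 95% intervals from counting error only, and fragment 1002274 runs from 0 of 27 molecules in clone 2 to 22 of 22 in clone 1.

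Pattern diversity between molecules was lower in both clones on average, and most of all at intermediate windows. Mean epipolymorphism over 224068 windows was 0.225 in the population (95% interval 0.219 to 0.230), 0.196 in clone 1 (0.192 to 0.201) and 0.198 in clone 2 (0.194 to 0.203). At 153253 windows under 20% in the population it was 0.133 in the population, 0.127 in clone 1 and, higher, 0.136 in clone 2, with overlapping intervals for clone 2 (0.133 to 0.140) and the population (0.130 to 0.137). At 55035 windows over 80% it was 0.318, 0.279 and 0.260. Both of these classes were chosen on the same population molecules that were measured, which can lower the population's value. The higher mean of clone 2 at windows under 20% may therefore come from that choice. At 13182 windows intermediate in a separate part of the population it was 0.727, 0.564 and 0.570. Mixed molecules, with both methylated and unmethylated CpGs in the window, made up 50.6% there in the population (49.0 to 51.9), 52.0% in clone 1 (50.3 to 53.6) and 52.9% in clone 2 (51.3 to 54.5). At 10 molecules per window, 4760 intermediate windows carried a mean of 4.83 patterns in the population, 3.35 in clone 1 and 3.39 in clone 2. The 2 commonest patterns took 68.5% of population molecules, 83.9% of clone 1 molecules and 83.5% of clone 2 molecules.

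Sites at either end of the scale departed from the population by under 1 percentage point on average. At 88061 CpGs with no methylated molecule in 1 random part of the population, methylated calls made up 1.53% in the rest of it (1.49 to 1.58), 2.08% in clone 1 (2.00 to 2.17) and 2.22% in clone 2 (2.14 to 2.31). At 69805 fully methylated CpGs, unmethylated calls made up 4.41% (4.35 to 4.47), 4.24% (4.17 to 4.31) and 3.84% (3.77 to 3.91).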

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

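The tests of amplification, of bisulfite conversion and of chance neighbours were chosen after the results they bear on were seen, and the tests of the mean shift, the shared counting error and copy loss were set beforehand.

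The clones had the same labelled number of divisions and differed from each other at 41997 CpGs and at 3188 fragments, by a direct test of the difference between them. Of the 3188 fragments, 200 lay in runs of at most 4 with adjacent numbers and the same direction; these made 104 pairs, while the highest of 1000 shuffles gave 15, and 7 pairs went in opposite directions. A lost chromosome copy in 1 clone would lower coverage where that clone is uniform, but the median log2 coverage there was -0.0634 (95% interval -0.122 to -0.00240). Where both clones were equally uniform, as with opposite complete states, clone 2 was taken as the uniform one. A copy lost in clone 1 would there count with the wrong sign, so this value does not decide on copy loss. The median log2 coverage of clone 1 relative to clone 2 in the runs was -0.0273 (-0.105 to 0.0254). That argues only against loss in the same clone at most of these fragments. The shuffles kept classes of CpGs per fragment but not the level, which adjacent fragments shared. Calls gathered at fragments at 20 to 80% in clone 2 (10.7%, against 2.46% of all), so the shuffles cannot decide on chance placement. The 104 pairs with the same direction against 7 with opposite ones still show that direction was shared between neighbours. That regional methylation states of the founder cells were carried through the divisions may account for the runs, and the design holds no other founder cells to test it.

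The mean level at intermediate CpGs was higher in both clones than in the population. Molecules with 2 or more reads and with 1 read differed by at most 0.320 percentage points at the same CpGs, under the 3.40 and 5.12 points of the shift, which argues against amplification bias. Excess methylated calls at unmethylated CpGs reached 6.47% of what incomplete conversion would need. A change in culture or division shared by both clones, and a different makeup of the population, might each account for it and stay open, since no library in the design separates them.

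Both clones also deviated from the population together at the same CpGs. Removing each clone's mean deviation by level and fragment class left a covariance ratio of 0.0359 (95% interval 0.0319 to 0.0406), so the common mean shift does not account for all of it. Setting the clones against separate parts of the population's molecules left 0.0419 (0.0359 to 0.0482), which argues against counting error of the shared library. A bias of the population library itself, or a change common to expanded cells, may remain as sources, because there was 1 population library.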

How the results depend on the processing

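The single-strand settings, the settings without rebuilt ends, without molecules with a last value above 0 and without strands over 25 molecules, and the windows chosen on part of the population were chosen after the data were seen, as were the overlap expected within classes, the calls by fragment class and level together and the calls against part of the population with their matched CpGs; all other alternatives were fixed before the data were examined. No paired analysis was possible because the 2 replicates of each clone share 1 deposited file and the population had 1 replicate, and no replicate could be left out for the same reason. Autosomes alone, promoter widths and the gene lists were not run, since the files give no coordinates. No ratio changed sign. Of the counts of calls, the ratios and epipolymorphism, 50 recomputed values stayed within 1.5 times the count or within the interval and 64 moved. Of the shares of higher calls, 61 stayed within 10 points and 5 moved. In clone 1 the majority of calls against the population turned from higher to lower in 3 of these, 45.2% and 42.3% of CpGs and 46.4% of fragments; in clone 2 they were 51.4% of CpGs and 54.4% of fragments. Few simulated changes of 50 points or less were called, but with only 200 CpGs changed the adjusted threshold was stricter than in the data.

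In the order clone 1 against the population, clone 2 against the population and clone 1 against clone 2, called CpGs numbered 9495, 7187 and 25828 with a coverage minimum of 20, and 2166, 1543 and 10269 with 30. Thinned to 10 molecules they were 217, 180 and 3988, and with 1 CpG per fragment 5548, 3975 and 12533, in both cases with less data by construction. Counting reads in place of molecules gave 50268, 52582 and 73058. It counts a molecule once per read, at 2.01, 1.34 and 1.67 reads per molecule in the population, clone 1 and clone 2. By construction more CpGs then reached the coverage minimum, 985557, 903111 and 964464. Reads of 1 molecule are not independent, so these calls overstate the evidence. The plus strand alone gave 2283, 1647 and 13261 and the minus strand 2394, 1643 and 13227. Called fragments numbered 521, 364 and 1481 with at least 30 molecules, 3850, 2872 and 8438 by the deepest single CpG, 190, 175 and 946 on the plus strand and 236, 140 and 905 on the minus strand. Single strands hold fewer molecules; for the deepest CpG the cause was not tested.

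The variance ratios of clone 1 and clone 2 and the covariance ratio were 0.284, 0.290 and 0.0445 at population levels of 10 to 90%, 0.282, 0.292 and 0.0404 with a coverage minimum of 20, and 0.254, 0.264 and 0.0370 with selection and measurement on all molecules. They were 0.288, 0.287 and 0.0390 with 1 CpG per fragment, 0.288, 0.295 and 0.0391 on the plus strand, and 0.289, 0.296 and 0.0411 on the minus strand. The variance ratios alone moved to 0.313 and 0.323 at 40 to 60%, and to 0.236 and 0.232 with a coverage minimum of 30. Epipolymorphism of the population, clone 1 and clone 2 was 0.236, 0.206 and 0.208 with at least 20 molecules per window, 0.787, 0.579 and 0.585 in windows at 20 to 80%, and 0.727, 0.564 and 0.570 in windows chosen on part of the population. Windows at 20 to 80% cannot be uniform in the population, so its diversity there was higher by construction. Selection and measurement on all molecules lets in the regression to the mean that the separate parts avoid. The cause of the other moves was not tested.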

Other observations

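The lag correlations were chosen after the neighbouring calls were seen, and the tests between the clones and between strands were chosen after the lower diversity was seen; the bounds of each hypothesis test were set before its own value was seen.

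Fragment numbers followed an order along which methylation was shared: across 25039 pairs of adjacent fragments, the population's level correlated at r = 0.955 (95% interval 0.953 to 0.956), and across pairs 100 numbers apart at r = 0.0531. The difference between the clones correlated at r = 0.410 for adjacent fragments, 0.279 for 2 numbers apart, 0.148 for 3 and -0.0170 for 10. It was taken at intermediate fragments only, with 2121 adjacent pairs, so its reach cannot be ranked against that of the population's level. These correlations are across fragments of 3 libraries, and fragments are not independent replicates. Among the named fragments, 1002274, 1002276 and 1002279 lay within a few numbers of each other, and each was methylated on all molecules of clone 1 and on 0 of 27, 0 of 14 and 0 of 15 molecules of clone 2.

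Copying of each founder cell's mixed patterns through division is a candidate explanation of the lower pattern diversity of the clones at intermediate windows. Within a library, 2 mixed molecules of a window matched in 18.9% of pairs in the population, 42.8% in clone 1 and 42.2% in clone 2, a ratio of at least 2.23, which largely restates the lower diversity. A mixed molecule of clone 1 and one of clone 2 matched in 19.6% of pairs (95% interval 18.5 to 20.8), 1.04 times the population's, which argues against the same patterns being favoured in both clones. Mixed molecules on opposite strands, amplified apart, matched in 17.05% of pairs in the population, 42.3% in clone 1 and 41.3% in clone 2, a ratio of at least 2.42, which argues against 1 molecule counted under several tags. How far copying was exact, and how many patterns each founder cell held, stay open.

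The variance ratios of about 0.3 lay below the 0.503 of simulated clones that kept 2 founder alleles. Disorder within molecules might have lowered them, but the ratio was 0.252 in clone 1 and 0.274 in clone 2 where 20% or fewer population molecules were mixed, below the 0.344 and 0.339 where over 60% were. That is opposite in direction to what the hypothesis needs. Windows with few mixed molecules may also hold parent- or allele-specific methylation, left open below, which would lower the ratio there. The values therefore do not decide on disorder within molecules, and loss of the founder state during the divisions stays untested.

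Middle levels made of fully methylated and fully unmethylated molecules could reflect parent- or allele-specific methylation. In windows at 40 to 60%, most molecules were mixed, 60.5% in the population, 69.9% in clone 1 and 70.7% in clone 2. These were 5802, 9131 and 8029 windows, chosen in each library by its own level, so the shares cannot be compared between libraries. Of 427 fragments at 20 to 80% in the population with 20% or fewer mixed molecules there, 129 lay at 40 to 60% in clone 1, 127 in clone 2 and 52 in both, against 38.4 if independent, a ratio of 1.36 (two-sided Fisher's exact test, p = 0.00261). The excess was not particular to middle levels: 9 fragments lay at 10% or less in both clones, against 1.25 if independent, and 26 at 90% or more, against 6.44. The expected counts were not matched on population level, which spans 20 to 80% at these fragments. Clones that each followed that level could therefore give such excesses, whether or not allele-specific methylation adds to them. The p-value treats fragments as independent, although adjacent fragments shared their levels. The ratio fell between the bounds set beforehand, so that hypothesis stays open, and the files give no coordinates to look for known imprinted regions.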
